A study of Mus musculus with 6 samples.

How the data were processed

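Total RNA (200 ng per animal) of adult forebrain cortex was extracted with the miRVana PARIS kit, labelled with an Affymetrix whole-transcript kit and hybridised to 1 array per animal, per the labels' protocols. The 3 Dicer KO animals carry a CamKII-driven Cre transgene and 2 floxed Dicer alleles. The 3 controls are littermates that lack either the Cre transgene or 1 of the floxed alleles, and the labels do not say which control has which genotype. Groups and array numbers were taken from the sample labels, which call the arrays biological replicates, so p-values measure the spread between these animals.

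The deposited table holds 1 value per probe set and array, on the log2 scale, from about 1.93 to 14.8. RMA and limma are named in the submitters' processing notes, without versions; the background step and the probe set definition are not given in the sources used here. RMA shrinks differences of dim transcripts towards 0, and the 6 columns of deposited log2 values have nearly the same quantiles, so a shift common to most genes would not show. No value per probe and no detection call was used here, so signal over background is unknown, and the number of arrays limits the precision.

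The table has 35557 rows. A probe table made from the platform's annotation lists 23410 of them with a gene: 21789 with 1 gene symbol and 1621 with several, which were left out, as were the 12147 rows without a listed gene. Symbols can be old, so 21698 probe sets were renamed through their gene identifier in a table of mouse genes of assembly GRCm38.p6. A further 91 kept the symbol of the probe table. The table of mouse genes also gave the positions that define the chromosome 12 cluster of microRNA genes. For the 999 genes with several probe sets, the one with the highest mean over all 6 arrays was used, which left 19938 genes. Coordinates are not reported. Some genes of the fixed lists were not analysed here.

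Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, prior degrees of freedom 4.89), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, two-sided. Errors of differences are the moderated standard errors of that model. An exact permutation test of 3 against 3 arrays cannot give a two-sided p below 0.1, so none is reported for single genes. The 42 gene lists were fixed before the data were examined, from background knowledge of the brain, microRNA targets and tau biology, and none was chosen on these samples. Each list with at least 5 measured members was tested with camera at a preset correlation of 0.01, adjusted over the lists. Beside it stand camera with an estimated correlation and fry, which asks whether the genes of a list move 1 way or in either direction without comparing them with other genes. Members were counted over all genes tested and adjusted over the list alone. Lists overlap: Vim, for example, is a member of 3 lists and Dicer1 of 2. Sex-linked genes are given as values only.

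The genes named were set by a rule written before the data were examined: Dicer1, the 12 genes with the largest positive and the 12 with the largest negative changes past the threshold whose groups do not overlap, up to 4 members of smallest p per list, a set of genes of tau, amyloid and cell type biology regardless of their values, and sex-linked genes. Gene models without a proper name were only counted. Other genes named in the closing observations were chosen after their values were seen, and this is said there.

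The steps were tested on simulated data with the real genes' means and spreads. Of genes changed by 1 on the log2 scale 83.0% were called, of those changed by 0.5 34.4%, and 4.40% of calls were false (100 genes of each size in each of 5 runs over 19938 genes). Of 4 lists shifted by 0.3, 4 were found, and of 36 unshifted lists 0 passed. The noise was simulated independently for each gene, so this does not check camera on lists whose members vary together. In the real data the estimated correlation was 0.72 for the oligodendrocyte and myelin list, for example. Arrays were compared first: any pair differed in at least 35523 of the 35557 rows, so none was deposited more than once.

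Alternatives listed before the data were examined were the array number as a block, each array left out in turn, median centring, a second quantile normalization, leaving out the dimmer genes, averaging probe sets, testing every row, a trended and robust prior, array weights, an unmoderated test, a fold minimum of 1.5, a looser threshold of 0.1, an estimated correlation and fry. The sex of the animal as a covariate, and leaving out array 3 of both groups, were added after the data were seen.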

Results

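Gene expression was measured in adult forebrain cortex of C57BL/6 mice in which the CamKII promoter drives Cre recombinase in excitatory forebrain neurons. Dicer, the enzyme that cuts microRNA precursors into mature microRNAs, was to be deleted where both of its alleles carry loxP sites. Total RNA of 3 animals labelled Dicer KO and of 3 littermate controls was hybridised to 1 Affymetrix whole-transcript array each, so precision is limited by the number of arrays. The 6 arrays had median log2 values between 7.13 and 7.22. Pairs of arrays correlated with r between 0.9749 and 0.9915 across all 35557 probe sets, which are not independent replicates. Y-linked transcripts differed between animals. Eif2s3y, a translation factor gene on the Y chromosome, read 9.13 and 9.29 in labelled KO arrays 1 and 3 and 9.07 in control array 2, against 4.25 in labelled KO array 2 and 3.94 and 4.44 in control arrays 1 and 3. Xist, the transcript of the inactive X chromosome, was high in the complementary arrays, so the arrays labelled Dicer KO came from 2 males and 1 female and the control arrays from 1 male and 2 females. The series asks what loss of Dicer in adult neurons does to the cortex, with tau phosphorylation and neurodegeneration named in its title.

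Dicer1 itself read higher, not lower, in the arrays labelled Dicer KO. Its log2 expression was 9.58, 9.68 and 9.46 in those 3 arrays against 9.17, 9.21 and 9.18 in the controls, a mean of 9.57 ± 0.11 against 9.19 ± 0.018 (SD, n = 3 each). The difference of 0.39 ± 0.087 (SE), 1.31-fold, did not pass the threshold over all genes (limma adjusted p = 0.102). Dicer1 has a single probe set, and which of its exons that probe set reads was not examined here. Cells in which the driver is silent also keep the gene, so this value does not check the deletion or the labels. Directions below are therefore those of the arrays labelled Dicer KO.

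Transcripts of the microRNA machinery were higher as a group in the arrays labelled Dicer KO. Of the 18 measured members of the miRNA pathway proteins list, 14 had positive log2 changes, with a mean of 0.20. Tnrc6c, a GW182 protein that links Argonaute to mRNA decay, rose 1.68-fold, by 0.75 ± 0.092 (SE; adjusted p = 0.0286), the 1 member past the threshold over all genes. Adjusted over the list alone, 7 members passed and all 7 were higher. Ago1, an Argonaute protein, was at 0.60 ± 0.10 and Tnrc6a, another GW182 protein, at 0.56 ± 0.095, each with an adjusted p of 0.0549 over all genes, and without labelled KO array 3 Ago1 passed (adjusted p = 0.0416). The list passed camera's test with a preset correlation (adjusted p = 1.7e-05), but not with an estimated correlation (adjusted p = 0.470).

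The 300 miRNA genes on the array, whose probe sets can pick up precursor transcripts, had a mean change of 0.092, with 179 above 0 and none past the threshold over all genes or adjusted over the list alone. Mir30a was at 0.38 ± 0.082 and Mir124a-2 at 0.39 ± 0.10, while Mir218-1 was at -0.41 ± 0.094 (SE). This list passed camera (adjusted p = 0.0103; adjusted p = 0.555 with an estimated correlation). Its call was lost without control array 3, when the mean was 0.031, and without labelled KO array 2, when it was 0.055. The 19 measured miRNA host and cluster transcripts had a mean change of 0.13 (adjusted p = 0.0190; adjusted p = 0.470 with an estimated correlation). None of them passed over all genes, and 3 passed adjusted over the list alone: Ctdsp2 at 0.35 and Igf2 at 0.49 were higher and Sprn at -0.53 was lower. The adjusted p of this list was 0.0754 without labelled KO array 3, and without control array 3 it was 0.124.

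**Figure D1:**
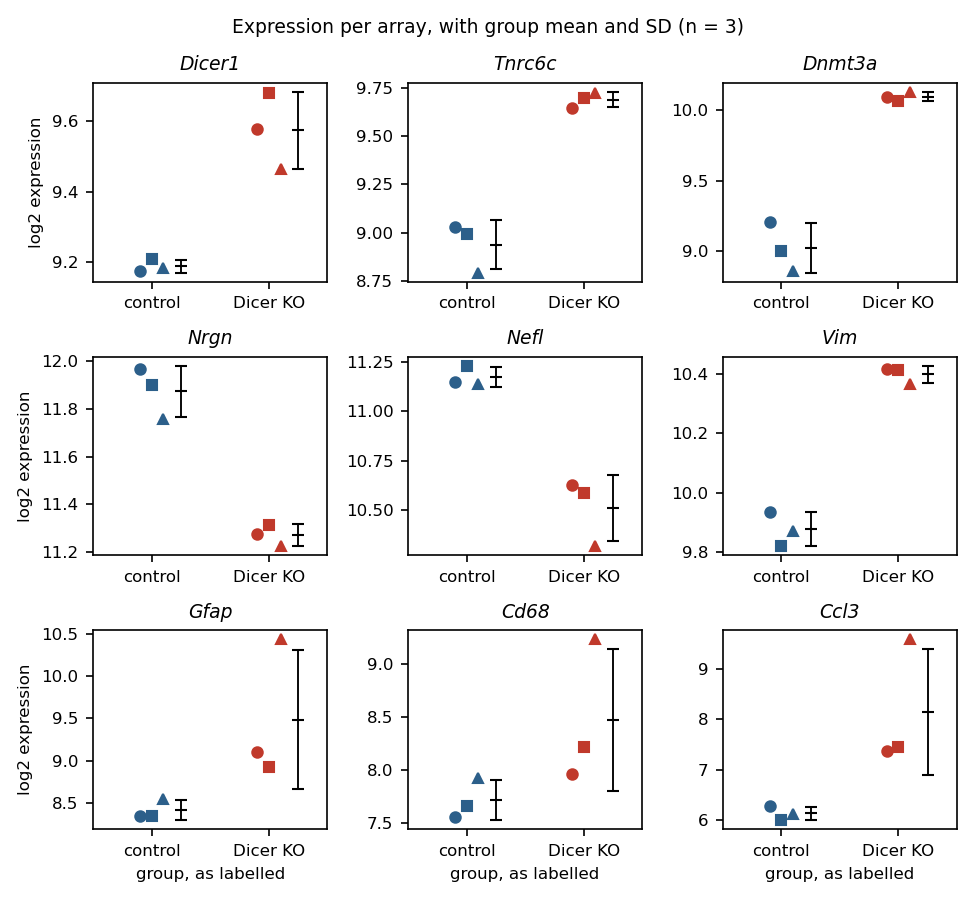
Log2 expression of 9 genes in each array, with controls in blue and arrays labelled Dicer KO in red (circle, square and triangle for arrays 1, 2 and 3), and the group mean with its SD (n = 3 each) beside the points; each panel has its own vertical range, which does not start at 0. Dicer1, Tnrc6c, Dnmt3a, Vim, Gfap, Cd68 and Ccl3 are higher and Nrgn and Nefl lower in every labelled KO array than in every control. For Gfap, Cd68 and Ccl3 labelled KO array 3 also stands well above the other labelled KO arrays.

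Across 19938 genes, 56 differed between the arrays labelled Dicer KO and the controls at an adjusted p under 0.05, 18 of them higher and 38 lower. Dnmt3a, a de novo DNA methyltransferase, rose 2.1-fold, by 1.07 ± 0.10 on the log2 scale (SE; adjusted p = 0.0190). Ankrd52, a regulatory subunit of a protein phosphatase that acts on Argonaute, rose 2.40-fold, by 1.27 ± 0.14 (adjusted p = 0.0207). Stc1, which encodes the secreted glycoprotein stanniocalcin, rose 2.05-fold, by 1.04 ± 0.10 (adjusted p = 0.0192). Smaller increases were measured for the choline transporter-like gene Slc44a5 at 0.83, the neuronal membrane protein gene Islr2 at 0.81, the sarcoglycan gene Sgcb at 0.79 and the imprinted gene Nap1l5 at 0.78. The others among the 12 largest were Ammecr1 at 0.76, the adhesion protein gene Cxadr at 0.75, the GW182 gene Tnrc6c at 0.75, the signalling adaptor gene Tab2 at 0.75 and the atlastin gene Atl3 at 0.66.

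Among the genes that fell, Tnnc1, the slow and cardiac troponin C, was 2.66-fold lower, at -1.41 ± 0.18 (SE; adjusted p = 0.0311). Cbln4, a secreted organiser of synapses, was 2.39-fold lower, at -1.26 ± 0.18 (adjusted p = 0.0408). Frzb, a secreted Wnt antagonist, was 2.37-fold lower, at -1.24 ± 0.12 (adjusted p = 0.0190). Camkk2, a calcium/calmodulin-dependent kinase that activates other kinases, was 2.02-fold lower, at -1.01 ± 0.13 (adjusted p = 0.0286). The matrix protein gene Abi3bp was at -1.19, the perineuronal net link protein gene Hapln4 at -0.98, the nicotinic receptor modulator gene Lynx1 at -0.97 and the secreted protein gene Scube1 at -0.95. Spink10 was at -0.99, the mTOR inhibitor gene Ddit4l at -0.89, the AMPA receptor-associated gene Syndig1 at -0.81 and the histone deacetylase gene Hdac9 at -0.76. Spink10 was dim, with log2 values from 4.70 to 5.98, where the array medians were 7.13 to 7.22. A further 3 called genes carry model names, and all 3 were lower.

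**Figure D2:**
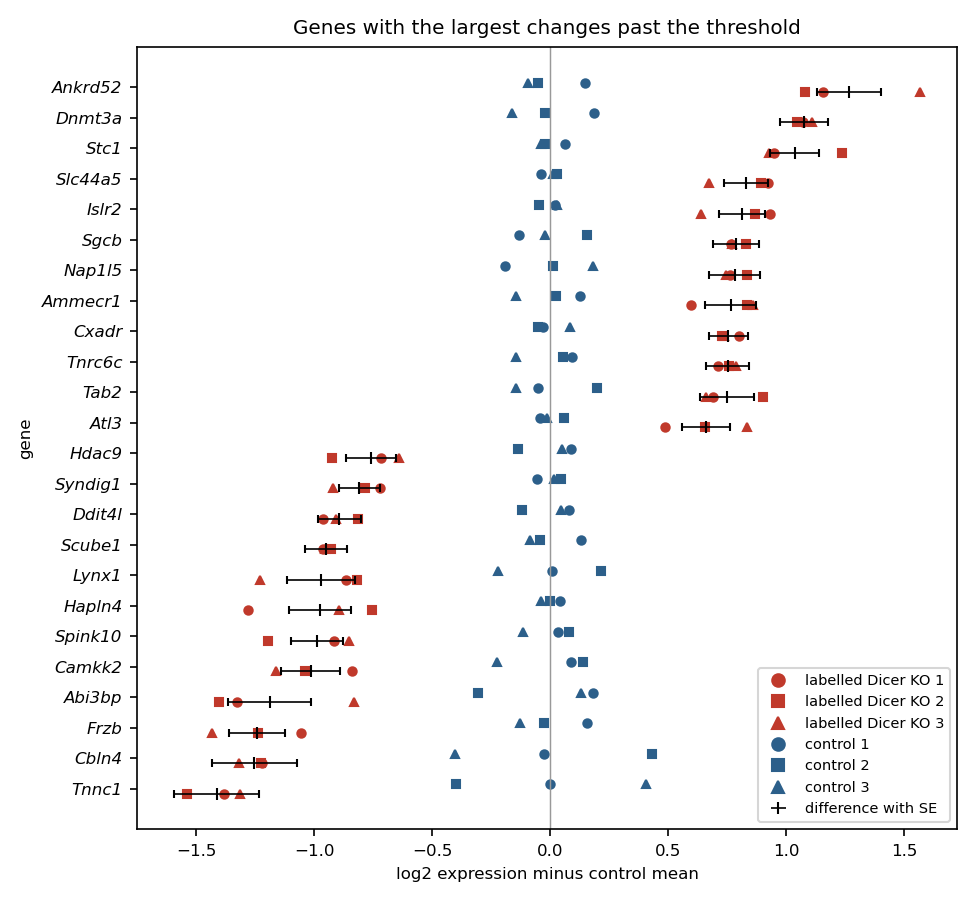
Log2 expression minus the control mean (horizontal axis) of the 12 genes with the largest increases and the 12 with the largest decreases past the threshold, with 1 point per array and a black bar for the difference between group means with its SE (n = 3 each). All labelled KO points lie on the same side of all control points for each gene, as the rule that chose them requires, from Ankrd52 at 1.27 to Tnnc1 at -1.41.

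In all 56 called genes every labelled KO array lay beyond every control array, which follows largely from their being called. Over all genes, 20.3% showed this separation, where chance gives 10%. At an unadjusted p under 0.05 there were 2871 genes, 1397 higher and 1474 lower, where 997 are expected by chance, and 320 genes passed an adjusted p of 0.1. The largest adjusted p among the calls was 0.0494, and the count depended on single arrays: limma called 129 genes without labelled KO array 3 and 0 genes without any 1 of the other 5 arrays, with 2197 to 2532 genes at an unadjusted p under 0.05 in those 5 fits. With the sex of the animal in the model, an alternative chosen after the data were seen, limma also called 0 genes (2292 at an unadjusted p under 0.05). Each of the 56 genes kept its direction and an unadjusted p under 0.05 in all of these fits. They were picked from the same arrays at a stricter threshold, so this was close to given and adds no support.

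Reported targets of brain microRNAs were tested as 6 lists, and 2 of them were higher in the arrays labelled Dicer KO. Of 26 measured miR-29 reported targets, 22 had positive changes, with a mean of 0.24 and array means of 0.24, 0.19 and 0.30 against -0.024 to 0.023 in the controls. Dnmt3a was the 1 member past the threshold over all genes, and 7 members, all higher, passed adjusted over the list alone. Among them were Sparc, a collagen-binding matrix protein, at 0.59 ± 0.11, Tet1, an enzyme that oxidises methylated cytosine, at 0.62 ± 0.14, and Bcl2l11, the cell death protein Bim, at 0.48 ± 0.11 (SE). As a group these targets passed camera (adjusted p = 2.35e-06), and their adjusted p was 0.470 with an estimated correlation. The list holds many matrix genes, and Col1a1, Col1a2 and Col3a1 are also meningeal and fibroblast markers. Those markers had array means of 0.30, 0.048 and 0.29 in the arrays labelled Dicer KO. Which cells the rise of the miR-29 reported targets comes from was not tested.

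Of 30 miR-124 reported targets, 23 had positive changes, with a mean of 0.17. Vim, the intermediate filament vimentin, rose 1.44-fold, by 0.52 ± 0.080 (SE; adjusted p = 0.0481), and 6 members, all higher, passed adjusted over the list alone, Itgb1, an integrin subunit, at 0.53 and Rdh10, a retinol dehydrogenase, at 0.32 among them. The list passed camera (adjusted p = 8.33e-05; adjusted p = 0.470 with an estimated correlation), and without labelled KO array 3 its mean was 0.094 (adjusted p = 0.0419). Its array means of 0.092, 0.097 and 0.31 in the arrays labelled Dicer KO stand beside 0.17, 0.14 and 0.39 for reactive astrocyte genes, of which Vim is also one, and 0.041, -0.045 and 0.33 for astrocyte markers. The other lists did not pass: miR-9 reported targets had a mean of 0.094 (adjusted p = 0.0995), miR-132 and miR-212 reported targets 0.073 (adjusted p = 0.0774), let-7 reported targets 0.015 (adjusted p = 0.572) and miR-15 family reported targets -0.052 (adjusted p = 0.221). In the miR-15 family list members went both ways, with the cyclin gene Ccnd2 at 0.77 ± 0.16 and the growth factor genes Bdnf at -0.43 ± 0.097 and Vegfa at -0.44 ± 0.11 (SE), and 2 were higher and 2 lower adjusted over the list alone. The call of miR-9 reported targets was gained without labelled KO array 2 (adjusted p = 0.0135), and that of miR-132 and miR-212 reported targets without labelled KO array 1 (adjusted p = 0.0345). Without labelled KO array 3 the mean of miR-9 reported targets was 0.024 (adjusted p = 0.798), that of miR-132 and miR-212 reported targets 0.031 (adjusted p = 0.350), that of let-7 reported targets -0.014 and that of miR-15 family reported targets -0.099 (adjusted p = 0.140). For miR-132 and miR-212 reported targets it was 0.037 without control array 1, for let-7 reported targets 0.034 and 0.025 without labelled KO arrays 1 and 2 and 0.0021 without control array 1, and for miR-15 family reported targets -0.034 and -0.024 without labelled KO arrays 1 and 2 and -0.030 without control array 3.

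Lists of synapse and neuronal cytoskeleton genes were lower in the arrays labelled Dicer KO. In labelled KO arrays 1 to 3, excitatory neuron markers averaged -0.12, -0.11 and -0.19, and reactive astrocyte genes 0.17, 0.14 and 0.39. In the glutamate receptors and postsynaptic density list, 20 of 22 measured members were below 0, with a mean of -0.21. Grm8, a metabotropic glutamate receptor, was 1.61-fold lower, at -0.69 ± 0.10 (SE; adjusted p = 0.0413), and 4 members, all lower, passed adjusted over the list alone, including the NMDA receptor subunit gene Grin2a at -0.35 and the scaffold gene Dlg4 at -0.34. In the synaptic vesicle and release genes list, 14 of 21 members were below 0, with a mean of -0.16. Rph3a, a Rab effector on synaptic vesicles, was 1.62-fold lower, at -0.70 ± 0.097 (SE; adjusted p = 0.0358), and 4 members, all lower, passed adjusted over the list alone, Unc13a at -0.41 and Syn1 at -0.34 among them. Both lists passed camera (adjusted p = 0.000113 and 0.00531), each had an adjusted p of 0.470 with an estimated correlation, and without labelled KO array 3 the synaptic vesicle and release genes had a mean of -0.13 (adjusted p = 0.0575).

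The list of tau and other microtubule-associated proteins also holds tubulin and neurofilament genes. Of its 21 measured members, 15 were below 0, with a mean of -0.17 (camera adjusted p = 0.00385, and 0.470 with an estimated correlation). The neurofilament light chain gene Nefl was 1.59-fold lower, at -0.67 ± 0.10 (SE; adjusted p = 0.0481). Adjusted over the list alone, 5 members were lower and 1 was higher, and among the lower ones were the neurofilament gene Nefm at -0.66 ± 0.14, Map1a at -0.49 ± 0.096 and the tubulin-binding protein gene Stmn2 at -0.40 ± 0.10 (SE). Without labelled KO array 2 the mean of tau and other microtubule-associated proteins was -0.12 (adjusted p = 0.0730). Mapt, which encodes tau, was at -0.062 ± 0.090 (SE; adjusted p = 0.810), a difference smaller than its error, and it was at -0.00016 without labelled KO array 2 and -0.12 without labelled KO array 3.

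Markers of excitatory neurons, the cells in which the driver acts, had a mean change of -0.14 over 24 members, which missed the threshold (excitatory neuron markers, adjusted p = 0.0546) and passed it without labelled KO array 1 or 2 or control array 1 or 3, with adjusted p between 0.0212 and 0.0400. Nrgn, the calmodulin-binding postsynaptic protein neurogranin, was 1.52-fold lower, at -0.60 ± 0.088 (SE; adjusted p = 0.0413), the 1 call over all genes, and adjusted over the list alone 2 members were lower and 1 higher. Lamp5 was at -1.19 ± 0.20 (adjusted p = 0.0549) and Nptx1, a neuronal pentraxin, at 0.41 ± 0.081 (SE; adjusted p = 0.0791). Camk2a, a kinase subunit abundant in excitatory neurons, was at -0.16 ± 0.13 and the vesicular glutamate transporter gene Slc17a7 at -0.098 ± 0.10 (SE), neither past the threshold. Camk2a was at -0.014 without labelled KO array 3, -0.26 without labelled KO array 2 and -0.098 without control array 2, and Slc17a7 lay between -0.17 (without control array 3) and -0.042 (without labelled KO array 3). Lamp5 passed without labelled KO array 3, at -0.94 (adjusted p = 0.0365). The 22 GABAergic interneuron markers had a mean of 0.0098 (adjusted p = 0.625), and Gad1, which makes GABA, was at 0.082 ± 0.13 (SE). In control array 1 these markers averaged 0.17 above the control mean, and 12 genes typical of olfactory bulb lay 1.06 above the other 5 arrays on average. Without control array 1 the GABAergic interneuron markers had a mean of 0.096 (adjusted p = 0.0306), and with any other single array left out it lay between -0.063 (without control array 2) and 0.040 (without labelled KO array 2).

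The title of the series names tau phosphorylation, so measured transcripts from lists of tau kinases, tau phosphatases and the ERK pathway were tested. None of these 3 lists passed in the arrays labelled Dicer KO. The 32 measured of 36 tau kinases had a mean of -0.064 (adjusted p = 0.171) and the 23 measured members of the tau phosphatases and related list a mean of -0.075 (adjusted p = 0.0546). For the ERK pathway, 24 of 31 listed genes were measured, with a mean of -0.066 (adjusted p = 0.316); the rest were not analysed here, so the list does not stand for the whole pathway. Ppme1, a methylesterase of a tau phosphatase, fell by 0.58 ± 0.085 on the log2 scale (SE; adjusted p = 0.0413), and adjusted over the list alone Ppp2r1b, a scaffold subunit of the same phosphatase, was also past the threshold, at 0.59 ± 0.13 (SE). Gsk3b was at 0.10 ± 0.086 and Cdk5 at -0.12 ± 0.14 (SE), both tau kinases and neither past the threshold. Cdk5 was at 0.046 without labelled KO array 3, and without labelled KO array 2 it was at -0.23 and Gsk3b at 0.050. The Cdk5 activators Cdk5r1 and Cdk5r2 were at -0.32 ± 0.099 and -0.35 ± 0.10 (SE). Mapk11, a p38 kinase, was at -0.54 ± 0.11 and was the 1 tau kinase past the threshold adjusted over the list alone. In the ERK pathway list, Etv5, a transcription factor, was at -0.45 ± 0.087 and the small GTPase gene Nras at 0.46 ± 0.095 (SE), the 2 members past the threshold adjusted over the list alone, and no member passed over all genes. Tau kinases passed without labelled KO array 2 (mean -0.11, adjusted p = 0.00652) and without control array 3 (mean -0.080, adjusted p = 0.0397), and tau phosphatases and related passed without labelled KO array 1 or 2 or control array 1, with means of -0.089, -0.099 and -0.093. Without labelled KO array 3 the mean of tau kinases was -0.017 (adjusted p = 0.992) and that of tau phosphatases and related -0.037 (adjusted p = 0.593), and without control array 2 that of tau kinases was -0.041 (adjusted p = 0.743). The ERK pathway mean was -0.0073 without control array 3, -0.040 without labelled KO array 1 and -0.11 without labelled KO array 3, and the list passed in none of these fits.

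Genes of amyloid precursor processing were slightly higher in the arrays labelled Dicer KO, with 18 of 21 members above 0 and a mean of 0.13 (adjusted p = 0.00488; adjusted p = 0.470 with an estimated correlation). No member passed, either over all genes or adjusted over the list alone. Apoe, a lipid carrier made mostly by astrocytes, was at 0.37 ± 0.096, the gamma-secretase subunit gene Aph1a at 0.25 ± 0.085 and the peptidase gene Ide at 0.48 ± 0.16 (SE). App, the precursor itself, was at 0.067 ± 0.079 and Bace1, the beta-secretase, at 0.087 ± 0.097 (SE); with single arrays left out Bace1 lay between 0.035 (without control array 2) and 0.16 (without labelled KO array 2), and App was at 0.044 without control array 1. Ide was at 0.31 without labelled KO array 3. Without labelled KO array 3 the mean of amyloid precursor processing was 0.080 (adjusted p = 0.0575).

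The 34 activated microglia genes had a mean of 0.35 in the arrays labelled Dicer KO and 32 members above 0, but their array means were 0.065 and 0.093 in labelled KO arrays 1 and 2 and 0.90 in array 3. Ccl3, a chemokine, was at 7.38, 7.45 and 9.58 against 6.27, 6.01 and 6.11 in the controls, a difference of 2.01 ± 0.49 (SE; adjusted p = 0.125). Cd68, a lysosomal protein of phagocytes, was at 7.96, 8.22 and 9.24 against 7.56, 7.66 and 7.93, a difference of 0.75 ± 0.28 (SE; adjusted p = 0.267). Ccl3 passed at 1.28 without labelled KO array 3 (adjusted p = 0.0110), and Cd68 was then at 0.37 (adjusted p = 0.216). No member of the list passed over all genes or adjusted over the list alone. It passed camera (adjusted p = 8.87e-06; adjusted p = 0.555 with an estimated correlation), and without labelled KO array 3 the mean of the activated microglia genes was 0.079 (adjusted p = 0.167). General microglia markers did not pass, with a mean of -0.0056 over 24 members (adjusted p = 0.971) and array means of -0.16, -0.33 and 0.48. Tmem119 was at -0.29 ± 0.098 and Aif1 at -0.0082 ± 0.13 (SE). The microglia markers had a mean of -0.25 without labelled KO array 3 (adjusted p = 0.0021), and with any other single array left out it lay between -0.073 (without control array 1) and 0.16 (without labelled KO array 2).

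Interferon-induced genes were higher in all 3 arrays labelled Dicer KO. The 28 members of the interferon response list had a mean of 0.37, with 24 above 0 and array means of 0.12, 0.36 and 0.64 against -0.038 to 0.070 in the controls. None passed over all genes and 6, all higher, passed adjusted over the list alone. They included the antiviral genes Ifit3 at 0.99 ± 0.17 and Ifit1 at 0.87 ± 0.22, the GTPase gene Iigp1 at 0.71 ± 0.13 and the chemokine gene Cxcl10 at 1.24 ± 0.27 (SE). As a list they passed camera (adjusted p = 1.75e-08; adjusted p = 0.470 with an estimated correlation), and without labelled KO array 3 the interferon response had a mean of 0.24 (adjusted p = 7.21e-05). The 18 complement genes had a mean of 0.25 (adjusted p = 0.00723; adjusted p = 0.509 with an estimated correlation), with the complement component genes C4b at 1.24 ± 0.27 and C4a at 0.67 ± 0.17 (SE), the 2 members past the threshold adjusted over the list alone. These 2 genes are near-identical copies, so their probes may not tell them apart. The 15 antigen presentation genes had a mean of 0.16 (adjusted p = 0.0157; adjusted p = 0.514 with an estimated correlation), and adjusted over the list alone 3 were higher, among them the peptide loading genes Tapbp at 0.54 and Tap1 at 0.39, and Psmb10, a proteasome subunit, was lower at -0.28. Without labelled KO array 3 the complement mean was 0.095 (adjusted p = 0.189) and the antigen presentation mean 0.10 (adjusted p = 0.174).

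Reactive astrocyte genes had a mean change of 0.23 over 30 members, 22 of them above 0, with array means of 0.17, 0.14 and 0.39 in the arrays labelled Dicer KO. Vim was past the threshold over all genes, and 7 members, all higher, passed adjusted over the list alone, including the serpin gene Serpina3n at 0.66 ± 0.15 and the oncostatin M receptor gene Osmr at 0.65 ± 0.15 (SE). These genes passed camera as a list (adjusted p = 0.000112; adjusted p = 0.470 with an estimated correlation). Gfap, the intermediate filament of astrocytes, was at 9.10, 8.92 and 10.4 against 8.34, 8.35 and 8.55, a difference of 1.07 ± 0.33 that did not pass (SE; adjusted p = 0.196) and that was 0.60 without labelled KO array 3 (adjusted p = 0.0550). General astrocyte markers had a mean of 0.11 over 21 members (adjusted p = 0.00755; adjusted p = 0.614 with an estimated correlation), with the gap junction genes Gjb6 at 0.48 and Gja1 at 0.44 and no member past either adjustment. Labelled KO array 3 averaged 0.33 for the astrocyte markers, whose mean was -0.0018 without it (adjusted p = 0.704), 0.19 without labelled KO array 2 and 0.069 without control array 1.

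**Figure D3:**
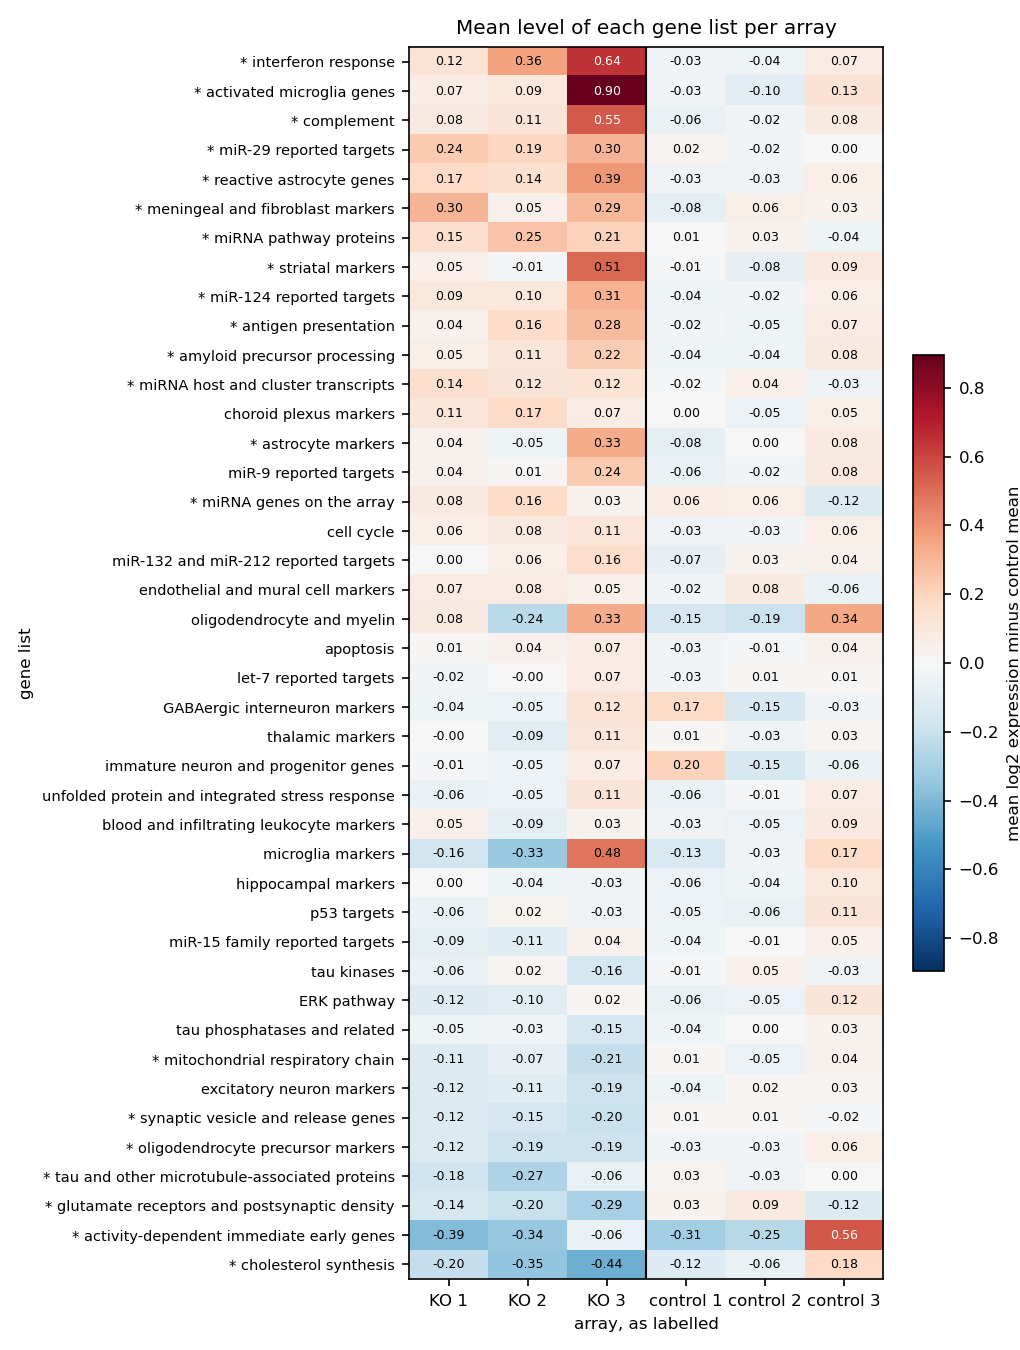
Mean log2 expression minus the control mean of the measured members of each of 42 gene lists (rows) in each of the 6 arrays (columns; red above, blue below the control mean), sorted by the mean change, with an asterisk for lists past camera's adjusted p of 0.05 with a preset correlation. Labelled KO array 3 stands at 0.90 for activated microglia genes and 0.64 for the interferon response, and control array 3 at 0.56 for activity-dependent immediate early genes.

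Cholesterol synthesis genes were lower in the arrays labelled Dicer KO. Of 20 measured members, 19 were below 0, with a mean of -0.33 and array means of -0.20, -0.35 and -0.44 against -0.12, -0.061 and 0.18 in the controls. None passed over all genes, and 9, all lower, passed adjusted over the list alone. Stard4, a sterol transfer protein, was at -0.78 ± 0.14, Hmgcs1, an early enzyme of the pathway, at -0.61 ± 0.14, Nsdhl, a late one, at -0.47 ± 0.11, and Srebf2, the transcription factor that drives the pathway, at -0.42 ± 0.090 (SE). The list passed camera (adjusted p = 1.75e-08; adjusted p = 0.470 with an estimated correlation).

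The 32 genes of the mitochondrial respiratory chain had a mean of -0.13, with 23 below 0. Cycs, which encodes cytochrome c, was 1.42-fold lower, at -0.50 ± 0.078 (SE; adjusted p = 0.0483), and 5 members, all lower, passed adjusted over the list alone, among them the cytochrome oxidase subunit genes Cox5a at -0.48, Cox7b at -0.47 and Cox6a1 at -0.34. The list passed camera (adjusted p = 0.00125; adjusted p = 0.514 with an estimated correlation), and without labelled KO array 3 the mitochondrial respiratory chain had a mean of -0.093 (adjusted p = 0.131).

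Activity-dependent immediate early genes had a mean of -0.26 in the arrays labelled Dicer KO, with 23 of 28 members below 0. The array means were -0.39, -0.34 and -0.056 against -0.31, -0.25 and 0.56, so control array 3 stood above the other 5 arrays. Adjusted over the list alone 6 members were lower and 1 higher, and none passed over all genes. The transcription factor gene Egr3 was at -0.54 ± 0.094, the neurotrophin gene Bdnf at -0.43 ± 0.097 and the clock gene Per1 at 0.58 ± 0.14 (SE). This shift passed camera (adjusted p = 0.00125; adjusted p = 0.598 with an estimated correlation). Without control array 3 the mean of the activity-dependent immediate early genes was 0.019 (adjusted p = 0.890), and without control array 1 it was -0.41.

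Lists of cell death, stress and division did not pass. Apoptosis genes had a mean of 0.039 over 29 members (adjusted p = 0.256) and of 0.025 without control array 1 (adjusted p = 0.282), with Cycs as the 1 call over all genes. Adjusted over the list alone, Bcl2l11 was also past the threshold, and Bcl2, an inhibitor of apoptosis, was at -0.30 ± 0.11 (SE; adjusted p = 0.261 over all genes). The 26 p53 targets had a mean of -0.024 (adjusted p = 0.795). Ddit4l fell by 0.89 ± 0.092 (SE; adjusted p = 0.0192), and Trp53inp1, at 0.67 ± 0.13 (SE), was higher adjusted over the list alone and passed over all genes without labelled KO array 3 (adjusted p = 0.0187). With single arrays left out the p53 targets lay between -0.056 (without control array 2) and 0.032 (without control array 3). The 36 cell cycle genes had a mean of 0.082 (adjusted p = 0.0774), with none past the threshold over all genes. Adjusted over the list alone 5 were higher, Ccne2 at 0.48 and Ccna2 at 0.56 among them, and E2f1, a transcription factor of S phase entry, was lower at -0.37. The adjusted p of the cell cycle list was 0.0354 without labelled KO array 2. The unfolded protein and integrated stress response list had a mean of 0.0011 over 28 members (adjusted p = 0.940), with Atf4 at -0.33 and the cystine transporter gene Slc7a11 at 0.67, and 2 members, both higher, past the threshold adjusted over the list alone. Immature neuron and progenitor genes had a mean of 0.0012 over 23 members (adjusted p = 0.315), with Vim as the 1 call and Sox11 at 0.44. In control array 1, where olfactory bulb genes were high, this list averaged 0.20 above the control mean, and without that array the immature neuron and progenitor genes had a mean of 0.10 (adjusted p = 0.0283), against -0.072 without control array 2.

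Markers of other cell types and neighbouring regions moved in part with the groups. The 12 oligodendrocyte precursor markers had a mean of -0.17, with 11 below 0 and array means of -0.12, -0.19 and -0.19 against -0.033 to 0.061 in the controls (adjusted p = 0.00385; adjusted p = 0.470 with an estimated correlation). Gpr17 was at -0.34 and Lhfpl3 at -0.29, and no member passed either adjustment. The oligodendrocyte and myelin list had a mean of 0.057 over 22 members (adjusted p = 0.390), with Mbp, a myelin protein, at 0.16 ± 0.16 (SE), from 0.0075 without labelled KO array 3 to 0.29 without control array 3. It varied within both groups, from -0.24 in labelled KO array 2 to 0.33 in array 3 and from -0.19 in control array 2 to 0.34 in array 3. The oligodendrocyte and myelin list passed without labelled KO array 2 (mean 0.21, adjusted p = 0.00319) and without control array 3 (mean 0.23, adjusted p = 0.00182), and its mean was -0.080 without labelled KO array 3, -0.018 without control array 1 and -0.039 without control array 2.

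The 17 meningeal and fibroblast markers had a mean of 0.21 (adjusted p = 0.000123; adjusted p = 0.470 with an estimated correlation) and array means of 0.30, 0.048 and 0.29 in the arrays labelled Dicer KO. None passed over all genes, and 4, all higher, passed adjusted over the list alone, including the matrix protein gene Fmod at 0.54 and the prostaglandin synthase gene Ptgds at 0.45. The 13 striatal markers had a mean of 0.18 (adjusted p = 0.00895; adjusted p = 0.555 with an estimated correlation), with Ppp1r1b at 0.29 and Pde10a at 0.41 (0.21 without labelled KO array 3). Their array means were 0.048, -0.010 and 0.51, and without labelled KO array 3 the striatal markers had a mean of 0.019 (adjusted p = 0.440), and without labelled KO array 2 a mean of 0.28. Endothelial and mural cell markers (mean 0.064, adjusted p = 0.0960), choroid plexus markers (0.12, adjusted p = 0.625), hippocampal markers (-0.024, adjusted p = 0.808), thalamic markers (0.0042, adjusted p = 0.601) and blood and infiltrating leukocyte markers (-0.0025, adjusted p = 0.958) did not pass. Endothelial and mural cell markers passed without control array 2 (mean 0.10, adjusted p = 0.0125) and had a mean of 0.036 without control array 3 (adjusted p = 0.641). Ttr, a choroid plexus transcript, was at 9.85, 10.95 and 8.30 in labelled KO arrays 1 to 3 against 8.73, 8.34 and 8.18 in the controls. Its difference of 1.28 did not pass (limma adjusted p = 0.319). Without labelled KO array 2 the difference was 0.66, and without labelled KO array 3 it was 1.98 and passed (limma adjusted p = 0.0380).

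In all, 21 of the 42 lists passed camera with a preset correlation, 14 higher and 7 lower in the arrays labelled Dicer KO. None passed with an estimated correlation (smallest adjusted p = 0.470, 3 lists at an unadjusted p under 0.05), and none passed fry's test of a shift in 1 direction (smallest adjusted p = 0.0702, 8 lists at an unadjusted p under 0.05). Fry's test of changes in either direction passed for 27 lists. It does not compare a list with other genes, and 2871 of all 19938 genes had an unadjusted p under 0.05 in limma. Passing it therefore does not set a list apart from other genes. Without labelled KO array 3, 13 lists passed, 12 of them among the 21. Mean, median or test differed in sign for 6 lists that did not pass, those of let-7 targets, GABAergic neurons, microglia markers, choroid plexus, p53 targets and the unfolded protein response.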

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

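Sex as a covariate and leaving out array 3 of both groups were chosen after the data were seen, and the other alternatives before. All 56 genes past the threshold kept their direction and an unadjusted p under 0.05 in each alternative that measured them. Since they were picked from the same arrays at a stricter threshold, this was close to given. Leaving out the dimmer genes measured 50 of them and called all 50. The number past the threshold was not stable. It stayed within 46 to 84 with a fold minimum, averaged probe sets, median centring, quantile normalization, and a trended and robust prior. It rose to 178 with dim genes left out, where 9969 genes were tested, to 1116 with array weights, to 89 with array 3 of both groups left out and to 320 at the looser threshold. It was 0 with all probe sets tested (35557 rows), 0 with an unmoderated test, and 0 with sex as a covariate, where 3725, 2403 and 2292 had an unadjusted p under 0.05. With single arrays left out it lay between 0 and 129. The largest adjusted p among the calls was 0.0494, and the cause of these changes of the count was not tested. The share of calls that were higher was 32.1%, 38.2% after median centring and 44.6% with array weights. With the array number as a block it was 49.3%, and with array 3 of both groups left out 49.4%, so the excess of lower calls was not stable. Signal over background was not used here, so what dimness limits is known only from the dim genes left out.

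Array numbers are shared between the groups, and no label says that they mark litters or batches. Deviations from the group means correlated at 0.089, 0.17 and 0.29 for arrays of the same number, 5 of 6 arrays correlated best with their own number, and the highest correlation of different numbers was 0.094, which is a hint from the data and not from the design. With the array number as a block, 215 genes passed, all 56 among them, and 21 lists, the same 21.

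Dicer1 was higher in the arrays labelled Dicer KO in every alternative. It passed only with array weights, at 0.390 (adjusted p = 0.0164, against a range of 0.0164 to 0.296 over its alternatives).

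Between 14 and 25 lists passed, except that 13 did without labelled KO array 3, which is the low end with single arrays left out and 25 the high end, and that 0 passed with an estimated correlation and 0 with fry (3 and 8 at an unadjusted p under 0.05). A list that was past the threshold changed its sign in 2 cases. Activity-dependent immediate early genes ranged from -0.415 to 0.0188 with single arrays left out, the high end without control array 3, and astrocyte markers from -0.0018 without labelled KO array 3 to 0.187. The remaining changes of sign were in results that did not pass, and except where arrays were left out the cause was not tested. Those of Uty and Xist, at 1.13 and -1.50 with group as the only term, were not in values near 0. With array weights they were let-7 reported targets at -0.0128, GABAergic interneuron markers at -0.0258, hippocampal markers at 0.0148, blood and infiltrating leukocyte markers at 0.0506, unfolded protein and integrated stress response at -0.0329 and immature neuron and progenitor genes at -0.0106. With array 3 of both groups left out, the same 6 were at -0.0070, -0.0582, 0.0287, 0.0230, -0.0218 and -0.0604, thalamic markers at -0.0358, p53 targets at 0.0370, Cdk5 at 0.0603 and Xist at 0.0101. With sex as a covariate, thalamic markers were at -0.0122, p53 targets at 0.0030, the unfolded protein and integrated stress response at -0.0105, Uty at -0.294 and Xist at 0.375. With dim genes left out, thalamic markers were at -0.0147 and the unfolded protein and integrated stress response at -0.0026; with median centring the latter was at -0.0010 and immature neuron and progenitor genes at -0.00096; with quantile normalization blood and infiltrating leukocyte markers were at 0.0098.

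With single arrays left out, ranges that crossed 0 were -0.0137 to 0.0342 for let-7 reported targets, -0.0631 to 0.0960 for GABAergic interneuron markers, -0.247 to 0.158 for microglia markers, -0.0799 to 0.228 for oligodendrocyte and myelin, -0.0517 to 0.0245 for hippocampal markers and -0.0484 to 0.0534 for thalamic markers. They were -0.0294 to 0.0415 for blood and infiltrating leukocyte markers, -0.0559 to 0.0324 for p53 targets, -0.0555 to 0.0349 for the unfolded protein and integrated stress response and -0.0717 to 0.103 for immature neuron and progenitor genes. Among named genes they were -0.150 to 0.0980 for Aif1, -0.230 to 0.0458 for Cdk5 and -0.0291 to 0.238 for Gad1.

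Over all named genes and alternatives, 2788 values kept direction and side of the threshold, 259 lost a call, 114 gained one and 9 changed sign. Over all lists the numbers were 568, 75, 23 and 46.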

Other observations

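The tests of the labels of Dicer1, of labelled KO array 3 and of the chromosome 12 microRNA cluster were chosen after the results were seen. Several genes past the threshold belong to no list, and the ones named here were chosen after their values were seen. In the arrays labelled Dicer KO, Rgs4, which shortens G protein signalling, was lower, at -0.67 ± 0.092, the small GTPase gene Diras2 at -0.67 ± 0.090 and the SNARE gene Vti1b at -0.62 ± 0.085 (SE). Hs3st2, a heparan sulfate sulfotransferase, was at -0.73 ± 0.10, Nme1, a nucleoside diphosphate kinase, at -0.61 ± 0.090, and Bag1, a co-chaperone, at -0.54 ± 0.084. The mitochondrial ribosomal protein gene Mrps18a was at -0.54 ± 0.083 and Tomm40l, related to the outer membrane import channel of mitochondria, at -0.68 ± 0.088. Ly6e, often induced by interferon, was lower, at -0.70 ± 0.092, while the interferon response list was higher on average. Among the genes that were higher were Hsd11b1, which regenerates active glucocorticoid, at 0.61 ± 0.093, the neuronal microtubule-binding gene Nav3 at 0.53 ± 0.083 and Cemip2, a membrane hyaluronidase, at 0.61 ± 0.088. All of these had an adjusted p under 0.05 and arrays of the groups apart.

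Dicer1 read 1.31-fold higher in the arrays labelled Dicer KO, which is the opposite of a plain loss of transcript. Swapped group labels would put reported microRNA targets lower in those arrays. The 115 measured targets of the 6 lists, without Dicer1, instead had a mean difference of 0.106, with 75 above 0 and array means of 0.060, 0.053 and 0.20 against -0.027, -0.012 and 0.039. That direction is not the one a swap would give, but limma's rotation test fry gave it a p of 0.121. Labelled KO array 3 also had the highest mean by far. The test therefore cannot decide, and the swap is not excluded. The probe set may also read mostly exons that recombination leaves in place, which needs values per probe, and Dicer1 had 1 probe set with 1 summary value.

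Labelled KO array 3 had the highest levels of activated microglia, complement, interferon and astrocyte genes. More white matter in its dissection was checked against control array 3, whose myelin genes were as high (difference -0.012). Activated microglia genes lay 0.768 lower there, beyond the 0.068 that bounds the central 95% of random lists of matched expression. Random lists hold genes that need not vary together, so these bounds are narrow for co-regulated lists. A single pair of arrays therefore does not exclude this source. Striatal tissue as the source of the whole interferon shift was checked in labelled KO array 2, where striatal markers were at -0.010. Interferon genes stood 0.357 above the control mean there, beyond the 0.077 that bounds random lists and above the -0.038 to 0.070 of the control arrays. The same limit of random lists holds, and a single array does not exclude this source either. More microglia in an unchanged state stays open. Activated genes stood 0.816 above the other 2 labelled KO arrays and general microglia markers 0.725. The gap was 0.0912 (permutation p = 0.557 over membership of the lists, two-sided). Against the control mean, the comparison made first, the gap was 0.418 in labelled KO array 3 (permutation p = 0.01005). It was 0.226 in labelled KO array 1 and 0.427 in labelled KO array 2. Both permutations are over genes that vary together, so their p does not measure the spread between animals. Striatal tissue as a source of the activated microglia genes cannot be told apart from a response to the deletion, since striatal markers stood at 0.512 in labelled KO array 3. An animal further along in a neurodegenerative response was not tested because no age or pathology was used here.

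Control array 1 had high levels of Eomes, Doc2g, Scgn and Frmd7, 2.24, 2.13, 2.35 and 3.11 above the mean of the other 5 arrays on the log2 scale. These genes were chosen after their values were seen. Olfactory bulb tissue in the dissection of control array 1 is a candidate source. On average, 12 other bulb genes lay 1.06 above the other 5 arrays, where random lists of matched expression gave -0.119 to 0.114. The limit of random lists given above holds here too. Of the 12, 11 were highest in this array. The values of Meis2 and Pbx3, whose probe sets read highest of the 12 in this array, were 10.9 and 9.64, against 9.73 to 10.1 and 7.57 to 8.21 in the other arrays, and cortex expresses some of the 12, Meis2 among them. No biological explanation was tested: the controls can differ in genotype, and the labels do not say which control has which.

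The chromosome 12 cluster of microRNA genes from Meg3 to Mirg had a mean change of 0.309 over 40 genes, 0.251 above the 0.058 of the 260 other microRNA genes (permutation p = 1e-05, the smallest that 100000 permutations can give, over genes that share transcripts). It did not separate the groups array by array, with 0.23, 0.48 and 0.22 in the labelled KO arrays against 0.16, 0.25 and -0.41, its fry p was 0.282, and without control array 3 the mean was 0.106. For Hapln4, a hypothesis set before its test was that other perineuronal net and parvalbumin cell genes fall with it. The 14 other genes had a mean of -0.068 ± 0.051 (SE over genes), with 11 below 0, 0 past the threshold in limma and a fry p of 0.247. By the rule set with the hypothesis, a fry p above the threshold with so small a mean fall counted against it. The error over genes still leaves room for a fall, so the test cannot decide. The mean also includes Tac1 at 0.39, which is on the striatal and GABAergic interneuron lists as well.

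The 6 arrays can be divided into 3 and 3 in 10 ways, and as many genes as the real 56 were called in 1 of them, the real one. The highest of the others was 4 genes, in the division that follows the sex of the animals, and the highest count of another division at an unadjusted p under 0.05 was 1812, against 2871. With 10 divisions the share cannot fall under 0.05. The 13768 rows outside the gene table held 0 rows past the threshold in limma, 832 at an unadjusted p under 0.05 and a smallest adjusted p of 0.143.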
